A study of Mus musculus with 12 samples.

How the data were processed

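RNA was measured by sequencing in neurosphere cultures from the ventral midbrain of CD-1 mouse embryos at embryonic day 11.5. Per the labels' protocols, the spheres were expanded for 3 days and then exposed for 5 h, in N2 medium, to the liver X receptor (LXR) agonist GW3965, to CT99021 (also called CHIR99021, an inhibitor of glycogen synthase kinase 3 beta), to both compounds, or to the solvent DMSO. Total RNA was isolated on columns and 0.5 µg was used for cDNA and Illumina TruSeq libraries, per the labels' protocols. Each of the 4 groups had 3 libraries, and the labels number them 1 to 3 in every group. The labels do not say whether a number marks a culture, a litter or a day.

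The authors deposited 1 table of raw read counts per feature for the 12 libraries, with no normalisation in its values, which were whole numbers. It held 23965 gene rows and 1217 rows of repeat families. Bowtie and the build mm9 are named in the submitters' processing notes. The roles and versions of these, the counting program, the annotation, the use of strand and the treatment of reads with several positions are not given in the sources used here. A total of 1047 gene rows carried a locus suffix, for 303 gene names, and 107 of these names had identical counts at every locus in every library, so values of near-identical copies, overlapping genes and antisense pairs are uncertain. Locus rows were kept apart. The base from which the table counts its positions is not stated, so a position is given as listed, in mm9. Repeat rows took 0.196% to 0.643% of all counts and stayed out of library sizes and gene tests. They were tested on their own with the gene totals and factors.

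Library totals over gene rows ran from 9646424 to 21314093 counts. Levels are given as CPM, each count relative to the library total, computed from the deposited counts with the factors below. Where a group had 0 counts a fold was set against a floor of 3 counts over the group, and where it had 1 to 3 counts the ratio carries an exact 95% binomial interval. Both cover counting error only, because the reads carry no molecular identifiers. No 2 libraries of a group agreed within sampling noise, with a chi-square per gene of 29.6 to 145.

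The main test, fixed before the data were examined together with the gene lists and the naming rule, was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3. All 12 libraries entered 1 fit with a mean per group, trimmed mean of M values (TMM) factors and the filterByExpr filter, which kept 15608 genes. Benjamini-Hochberg adjusted p under 0.05 counted as past the test. Contrasts were each treatment against control, the combination against each compound alone, and the interaction of the compounds on the log2 scale. Errors of log2 fold changes are standard errors, and errors of CPM are SD with n = 3.

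Whether replicate numbers pair the libraries was checked on deviations from the group means. All 18 pairs of libraries with the same number correlated, at r = 0.496 to 0.828 across genes (median 0.752), and each of the 12 libraries was closest to one of its own number. Pairs with different numbers from different groups lay between -0.677 and 0.241. The numbers were therefore treated as pairing the libraries, on evidence from the data and not from the labels, and the same fit with the replicate number as a block is given beside the fixed fit. The common biological coefficient of variation was 33.4% without and 12.7% with the block. Unless a sentence says otherwise, fold changes, standard errors and adjusted p are from the edgeR fit with the replicate block, and "rose" and "fell" refer to it.

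In total 26 gene lists were fixed beforehand. Each was described by the number of members past the test, the median log2 fold change and limma 3.58.1's camera on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Camera was repeated with a correlation estimated per list. That form was not tried on simulated lists, so a call lost with it does not show that a list stayed unchanged. Named genes were, per treatment against control, the 10 with the largest increase and the 10 with the largest decrease past the test among those at 1 CPM or more whose 3 libraries per group did not overlap (5 each way for the other contrasts). The rule also took Abca1, Srebf1, Axin2, Lef1, Th, Nr4a2, Lmx1a and Foxa2, and 2 to 4 members of each list. It was applied to the fit without and with the block. Any other gene named was chosen after its values were seen.

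Tested on simulated data with 200 changed genes among 15608, in CT99021 against control, the fit without the block made 89 calls, 8 of them false, and recovered 14% of genes changed by 1 log2 unit and 62% of those changed by 2. With the block it made 150 calls, 10 of them false, and recovered 74% and 84%. The fit without the block was tested on data simulated without replicate effects, and the fit with it on data simulated with them. These results therefore do not compare the fits on the same data, or describe the fit without the block on libraries paired by number. In other contrasts with the block, false calls were 14 of 151 for GW3965 and 6 of 151 for both compounds against control. They were 20 of 159 for both compounds against GW3965, 5 of 144 against CT99021 and 8 of 120 for the interaction. In 5 further simulations of CT99021 against control, each with 1 list raised, camera called 4 of the raised lists and, over all 5, 2 others. Genes were simulated without correlation between them, so this says little about camera's false calls for lists whose genes move together. Alternatives were other factors, no or a stricter filter, DESeq2 1.42.0, limma-voom, a fold threshold of 1.2, 2 groups only, each library left out, and several fits with the block that were added after the data were seen.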

Results

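Gene expression was compared by RNA sequencing in mouse ventral midbrain neurospheres under 4 conditions: DMSO control, the LXR agonist GW3965, the GSK3 beta inhibitor CT99021, and both compounds together, with 3 libraries each after 5 h. LXR is a nuclear receptor activated by oxysterols that controls cholesterol export and lipid synthesis, and inhibition of GSK3 beta stabilises beta-catenin, the effector of Wnt signalling. For replicates 1, 2 and 3, control libraries held 21314093, 19984548 and 12268085 gene counts and GW3965 libraries 21086005, 14645983 and 9646424. CT99021 libraries held 11964227, 16547405 and 14614448, and libraries with both compounds 19248735, 13660184 and 11499130. The labels do not say that replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical.

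Replicate number, not treatment, set the largest differences between libraries. The 1st principal component carried 49.7% of the variance and set the 4 libraries numbered 3 apart from the rest, the next carried 14.8% and parted numbers 1 and 2, and the one after that carried 14.2% and parted libraries with CT99021 from those without. Counts are given for the fit without and with the replicate number as a block, and genes are described from the latter. Lars2, a mitochondrial leucyl-tRNA synthetase gene, took 7.95% of the counts of CT99021 replicate 1 and 0.0336% to 0.142% in the other 11 libraries. A set of 5 libraries, those numbered 3 and GW3965+CT99021 replicate 2, stood apart from the other 7 in 215 gene rows by at least 1.5 times, and with other choices of the fifth library that number was at most 40. The set holds 1 library each of control, GW3965 and CT99021 and 2 with both compounds, and fits to the other 7 libraries, which hold 1 with both compounds, are given. No fit within the 5 was made. Fits to the 7 use a part of the same libraries and leave few libraries from which to estimate the spread. Genes called again in them are therefore no independent repeat.

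**Figure D1:**
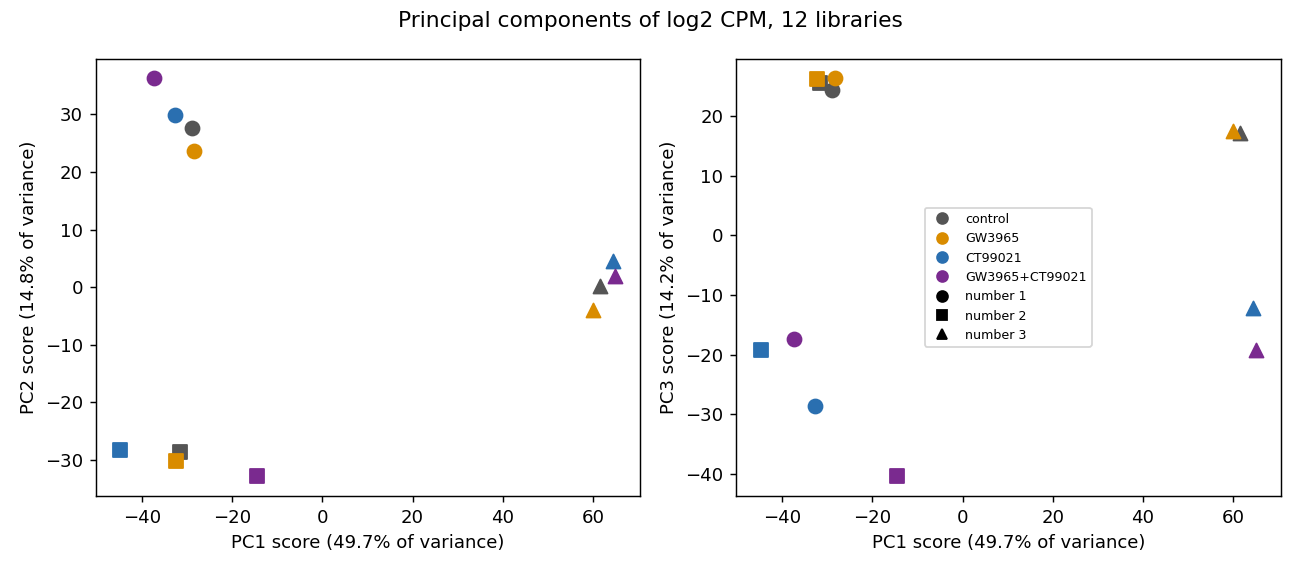
Principal component scores of the 12 libraries on log2 CPM, the 1st component against the next on the left and against the one after on the right, coloured by treatment and shaped by replicate number. The 4 libraries numbered 3 lie to the right of the others, of which GW3965+CT99021 replicate 2 is closest at -14.6.

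GW3965 against control asks which genes answer to LXR activation alone. Abca1, a cholesterol exporter listed at position 53043660 of chromosome 4, rose by a log2 fold change of 1.89 ± 0.17 (3.71-fold), from 59.8 ± 46.4 to 235 ± 209 CPM (SD, n = 3), and was higher in all 3 replicate pairs. Abcg1, a further sterol transporter (chromosome 17, position 31194538), rose by 1.92 ± 0.23, from 14.2 ± 5.33 to 52.3 ± 8.12 CPM. Srebf1, which encodes the transcription factor SREBP-1 of fatty acid synthesis (chromosome 11, position 60012590), rose by 1.40 ± 0.09, from 90.4 ± 14.2 to 238 ± 33.4 CPM. Scd1 and Scd2, which encode stearoyl-CoA desaturases, had log2 fold changes of 0.65 ± 0.10 and 0.79 ± 0.11 that did not pass (edgeR adjusted p = 0.135 for both).

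These were the 3 genes past the test with the block, with edgeR adjusted p of 0.00388 for Abca1, 0.0321 for Abcg1 and 2.6e-04 for Srebf1. Without the block edgeR called 0 of 15608 genes (23 at an unadjusted p under 0.05, against 386 with the block). Both counts lie under the share of 0.05 of genes expected with no change. The rise from 23 to 386 is therefore no measure of signal, and 0 calls do not show that no gene changed. DESeq2 called 2 without and 7 with the block, and limma-voom without the block 0. Srebf1 passed under all 20 alternatives of the fit with the block, Abca1 under 18 (not without control replicate 2 or 3) and Abcg1 under 10. For Abcg1 the highest adjusted p was 0.343. It did not pass without the libraries numbered 3, with a batch term, or without any 1 of the 3 controls, the 3 libraries with both compounds and GW3965 replicates 1 and 2. The count was 1 without control replicate 2 or without control replicate 3, 5 without CT99021 replicate 3, and 5 in the 7 libraries outside the set of 5.

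Of 16 measured LXR target genes, 3 rose and 0 fell, or 5 and 0 when adjusted over the list alone. The list was higher as a group (median log2 fold change 0.30, limma camera adjusted p = 5.5e-10), which was lost with an estimated correlation (adjusted p = 0.123), whereas in the fit without the block it kept an adjusted p = 0.00414 with an estimated correlation. Fatty acid synthesis genes were higher as a group (16 measured, median 0.14, 0 past the test and 3 higher when adjusted over the list alone, camera adjusted p = 1.0e-04), which was lost with an estimated correlation (adjusted p = 0.289). In this group Fasn, fatty acid synthase, had 488.0 ± 67.4 CPM in controls and 642.8 ± 64.8 with GW3965 (log2 fold change 0.40 ± 0.11, edgeR adjusted p = 0.959).

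Genes of the amino acid and endoplasmic reticulum stress response were higher and cholesterol synthesis genes lower by camera, and both differences were largest in the libraries numbered 3. The stress list of 12 genes, among them Ddit3, Trib3 and Chac1, had 0 members past the test, a median of 0.60 and a camera adjusted p = 2.5e-04 (adjusted p = 0.669 with an estimated correlation). Its median log2 ratio of GW3965 to control was -0.01 in replicate 1, 0.01 in replicate 2 and 1.78 in replicate 3, and without the libraries numbered 3 its camera adjusted p was 0.863 with the direction reversed. Cholesterol synthesis and uptake (24 genes, 0 past the test, median -0.13, camera adjusted p = 0.00309, and adjusted p = 0.669 with an estimated correlation) had ratios of 0.03, -0.05 and -0.42 in replicates 1, 2 and 3. Camera also placed lower the lists of mitosis, DNA replication, erythroid cells and Wnt targets, and higher the immediate early genes, each with 0 members past the test and with adjusted p of 0.669 with an estimated correlation. In replicate 3 the median ratios of mitosis, DNA replication, Wnt targets and immediate early genes were -0.42, -0.51, -0.63 and 0.94, while in replicates 1 and 2 they lay between -0.09 and 0.00. Erythroid genes had median ratios of -0.66, 0.05 and -0.26 in replicates 1, 2 and 3.

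**Figure D2:**
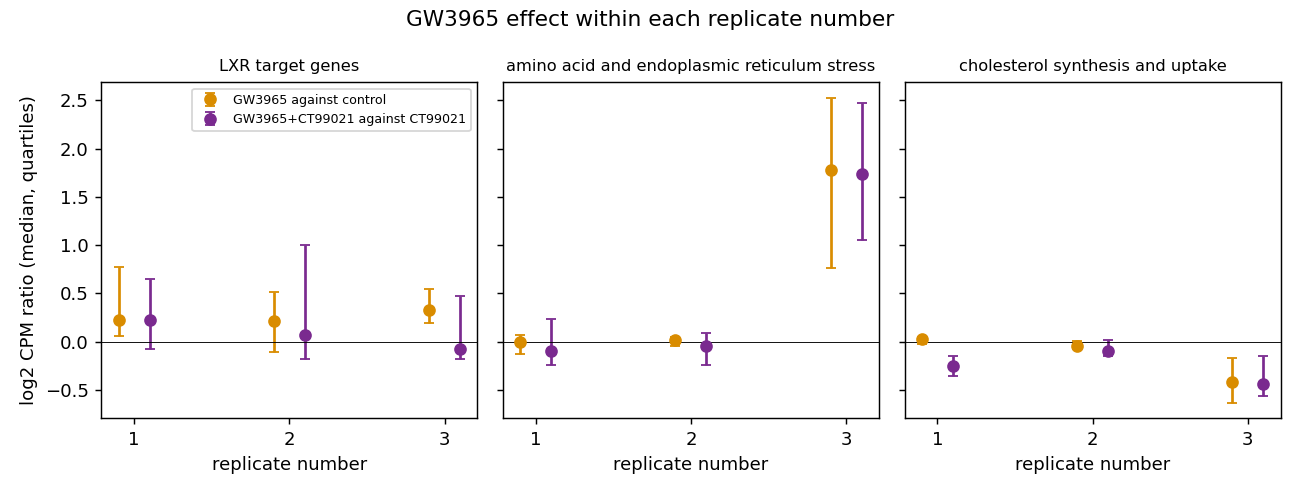
Median log2 ratio of CPM over the genes of a list within each replicate number, with quartiles as bars, for LXR targets, the stress list and cholesterol synthesis. Orange is GW3965 against control and purple GW3965+CT99021 against CT99021, and the stress list reaches 1.78 and 1.73 in replicate 3.

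CT99021 against control asks which genes answer to GSK3 beta inhibition. Axin2, a negative regulator of the pathway, rose by 1.68 ± 0.14, from 73.7 ± 33.7 to 253 ± 146 CPM (SD, n = 3), Nkd1 by 2.08 ± 0.20, Notum, which encodes a secreted Wnt deacylase, by 2.68 ± 0.16, and Lef1, a transcription factor that binds beta-catenin, by 1.63 ± 0.19, each higher in 3 of 3 replicate pairs. Wnt1 and Wnt3a, which encode Wnt ligands, changed by -1.95 ± 0.29 (15.1 ± 5.47 to 3.76 ± 0.67 CPM) and -2.30 ± 0.34. Olig2 and Olig1, transcription factors of the oligodendrocyte and ventral progenitor lineages, changed by -2.06 ± 0.29 and -1.87 ± 0.42, and Olig1 did not pass without any 1 of the controls or without CT99021 replicate 1 or 2.

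With the block edgeR called 2470 genes, 1285 higher and 1185 lower, and 225 of them changed by at least 1 log2 unit. Adjusted p was 1.4e-04 for Axin2, 3.9e-04 for Nkd1, 3.8e-05 for Notum, 0.00101 for Lef1, 0.00324 for Wnt1, 0.00299 for Wnt3a, 0.0023 for Olig2 and 0.0162 for Olig1. The fixed fit without the block called 9 genes, all lower (Nipal3, Fam100b, Gm7367, Atg13, Fam100a, Slc6a11, Zswim4, Bckdha and Maf1), and each of these also passed with the block. Fam100b and Gm7367 are listed at positions 116295307 and 116295426 of chromosome 11 with 50.8 and 50.5 CPM in controls, so they may not be separate measurements. Without any 1 of the control or CT99021 libraries the fit without the block called 3 or 4 (3 without control replicate 1, control replicate 3 or CT99021 replicate 1, and 4 without control replicate 2, CT99021 replicate 2 or CT99021 replicate 3), and limma-voom called 9. Fitted to the control and CT99021 libraries alone, edgeR without the block called 0. For Axin2 the adjusted p of edgeR without the block was 0.438. DESeq2 called 321 genes without and 2903 with the block. Groups did not overlap in 14.8% of tested genes, against 10% by chance for exchangeable libraries, which libraries paired by number are not.

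Among called genes at 1 CPM or more whose libraries did not overlap between the groups, the largest increases with CT99021 also held Ascl4, Sp5, Mybpc1, Tnfrsf11b, Mal, Cdh3, Neurog2 and Il20rb, and the largest decreases Frat1, Nipal3, Deptor, Ctgf, 1700084C01Rik and A930001N09Rik. Dkk4, a secreted Wnt inhibitor, had 1 count in the 3 control libraries together and 89 in those with CT99021, a ratio of 111 with a counting interval of 19.3 to 4415. Frat1, which encodes a GSK3 binding protein, went from 6.65 ± 0.11 to 0.72 ± 0.31 CPM (log2 fold change -3.17 ± 0.45, edgeR adjusted p = 0.00262). Nipal3 went from 27.8 ± 2.87 to 5.69 ± 1.62 CPM (-2.32 ± 0.14, edgeR adjusted p = 3.7e-05 with and 0.013 without the block).

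**Figure D3:**
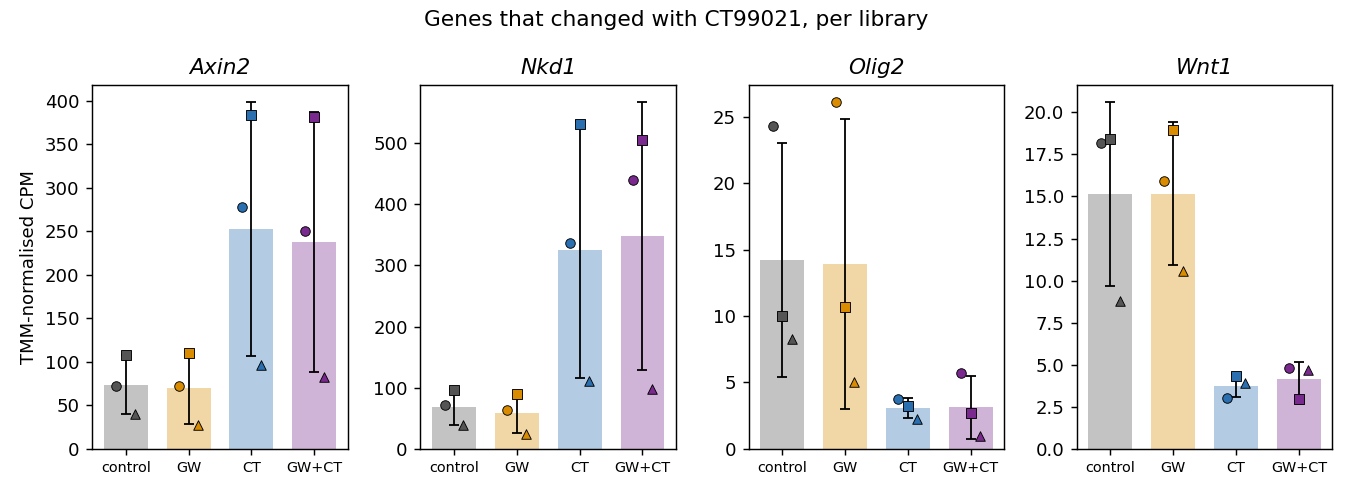
TMM-normalised CPM of Axin2, Nkd1, Olig2 and Wnt1 in the 4 groups. Bars are means, error bars SD (n = 3) and points the libraries by replicate number, and Olig2 lies at 14.2 CPM in controls and 3.07 with CT99021.

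Of 16 measured Wnt target genes, 10 rose with CT99021 and 1, Myc, fell (12 and 1 adjusted over the list alone), with a camera adjusted p = 1.6e-07. That call was lost in camera with an estimated correlation (adjusted p = 0.777), a form that left 0 of the fixed lists in every contrast with the block. The loss does not bear on the calls of single genes. Fatty acid synthesis genes were higher (6 of 16 rose and 0 fell, camera adjusted p = 0.00766, and adjusted p = 0.777 with an estimated correlation), with Scd1 at 0.73 ± 0.10 and Fasn at 0.61 ± 0.11. Of 24 cholesterol genes 6 rose, among them Lss (0.83 ± 0.18), and 0 fell (camera adjusted p = 0.00595, and adjusted p = 0.840 with an estimated correlation). LXR targets did not move together: Srebf1 and Lpcat3 rose by 0.42 ± 0.09 and 0.40 ± 0.08, Abcg1 fell by 1.08 (not past the test without control replicate 1, control replicate 2 or CT99021 replicate 1), and the camera adjusted p was 0.972. Of these genes Lss did not pass without control replicate 1 or 2 or CT99021 replicate 1 or 2, Srebf1 without control replicate 2 or CT99021 replicate 2, and Lpcat3 without control replicate 2.

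Neural progenitor genes were lower with CT99021: of 15 measured, Sox1, Sox3, Sox2 and Nes fell and 0 rose (Sox1 -0.67 ± 0.09, Sox3 -0.99 ± 0.17, camera adjusted p = 0.00766, and adjusted p = 0.840 with an estimated correlation). Among 8 proneural factors 1 rose (Neurog2, by 2.04 ± 0.28) and 1 fell, with a median of -0.15. In the list of floor plate and dopaminergic progenitors, 3 of 17 fell (Wnt1, Lmx1b and Rspo2), while Lmx1a, Foxa2 and Nr4a2, regulators of dopaminergic fate, had changes of 0.19 ± 0.21, -0.25 ± 0.13 and 0.12 ± 0.17 that did not pass. Th, the rate-limiting enzyme of dopamine synthesis, was scarce in every group and went from 1.23 ± 0.47 to 0.48 ± 0.22 CPM (log2 fold change -1.33 ± 0.36, edgeR adjusted p = 0.0315), and it passed under 10 of 20 alternatives, not without any 1 of the control or CT99021 libraries. The mitosis list was lower as a group (2 of 18 fell, camera adjusted p = 0.00766, and adjusted p = 0.854 with an estimated correlation).

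The count of CT99021 calls with the block depended on single libraries. It was 652 without control replicate 2, 747 without control replicate 1, 1075 without CT99021 replicate 1 (the library with high Lars2), 1114 without CT99021 replicate 2, 3869 without the libraries numbered 3 and 5398 in the 7 libraries outside the set of 5, where 2396 of the 2470 genes were called again.

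GW3965+CT99021 against control asks what both compounds change together. Srebf1 rose by 1.51 ± 0.09, to 258 ± 27.2 CPM, Abca1 by 1.79 ± 0.17, Axin2 by 1.56 ± 0.14, Notum by 2.55 ± 0.16 and Nkd1 by 2.16 ± 0.20. Scd1 rose by 1.28 ± 0.10, from 96.6 ± 6.58 to 236 ± 35.6 CPM, against 159.8 ± 15.3 with CT99021 alone and 153 ± 22.8 with GW3965 alone. Frat1 (-3.29 ± 0.46), Fn3k (-2.85 ± 0.41), Nipal3 (-2.55 ± 0.14), Olig1 (-2.45 ± 0.43), Olig2 (-2.24 ± 0.29) and Wnt1 (-1.82 ± 0.29) fell.

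With the block edgeR called 3163 genes, 1766 higher and 1397 lower, with adjusted p of 3.0e-05 for Srebf1, 2.7e-04 for Abca1, 2.0e-04 for Axin2, 7.6e-05 for Scd1 and 0.00128 for Olig2. Without the block it called 18, of which 3 were higher (9, 8 and 9 without control replicates 1, 2 and 3, and 9, 4 and 11 without GW3965+CT99021 replicates 1, 2 and 3), and Srebf1 and Scd1 were past the test in that fit too, with adjusted p of 0.00843 and 0.0081. DESeq2 called 573 without and 3494 with the block. The count with the block was 1526 without GW3965+CT99021 replicate 2, 1175, 1326 and 2054 without control replicates 2, 1 and 3, 1539 with a batch term for the set of 5, and 2959 in the other 7 libraries, which hold a single library with both compounds.

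Of 16 fatty acid synthesis genes 8 rose and 0 fell, with Scd2 at 1.12 ± 0.11, Fasn at 0.94 ± 0.11 and Acaca at 0.69 ± 0.08 (camera adjusted p = 3.0e-04, and adjusted p = 0.482 with an estimated correlation). Of 16 Wnt targets 8 rose and 1 fell (camera adjusted p = 1.3e-05, and adjusted p = 0.482 with an estimated correlation), and of 16 LXR targets 6 rose and 1 fell (camera adjusted p = 0.173). Among 15 neural progenitor genes 6 fell and 1, Slc1a3, rose (camera adjusted p = 0.00217, and adjusted p = 0.482 with an estimated correlation), and of 15 genes of other midbrain neurons 5 fell, among them Gad2, Gata3 and Tal1 (camera adjusted p = 0.00322, and adjusted p = 0.484 with an estimated correlation). Of 10 genes of mesenchyme and pericytes, markers of cells outside the neural lineage, 4 rose (Twist1, Foxc1, Col3a1 and Col1a2; camera adjusted p = 0.00881, and adjusted p = 0.531 with an estimated correlation). Foxc1 and Col3a1 did not pass without control replicate 1 or 2, and Col1a2 passed under 10 of 20 alternatives, not without any 1 of the controls or without replicate 1 or 2 of CT99021, replicate 1 or 2 of GW3965+CT99021 or replicate 1 of GW3965. The median log2 ratio of this list, GW3965+CT99021 to CT99021, was 1.22 in replicate 2, a library of the set of 5, against 0.39 in replicate 1 and -0.15 in replicate 3. Lists of other cell types were lower by camera: erythroid cells (2 of 10 fell, adjusted p = 0.00262, and adjusted p = 0.531 with an estimated correlation) and microglia (1 of 9 fell, 0.024 and 0.531). The oligodendrocyte lineage list was lower too (3 of 8 fell, 0.024 and 0.482). Its members Olig1 and Olig2 are also factors of ventral progenitors, so this need not concern another cell type. Camera also placed lower dopaminergic neurons (2 of 11 fell, adjusted p = 0.0158, and adjusted p = 0.482 with an estimated correlation), floor plate and dopaminergic progenitors (3 of 17 fell, 0.0421 and 0.531), pan-neuronal genes (4 of 14 fell and 1 rose, 0.0209 and 0.531), the Notch pathway (3 of 15 fell, 0.0282 and 0.531) and mitosis (2 of 18 fell, 0.00103 and 0.531), and higher the stress list (1 of 12 rose, 0.0209 and 0.558).

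**Figure D4:**
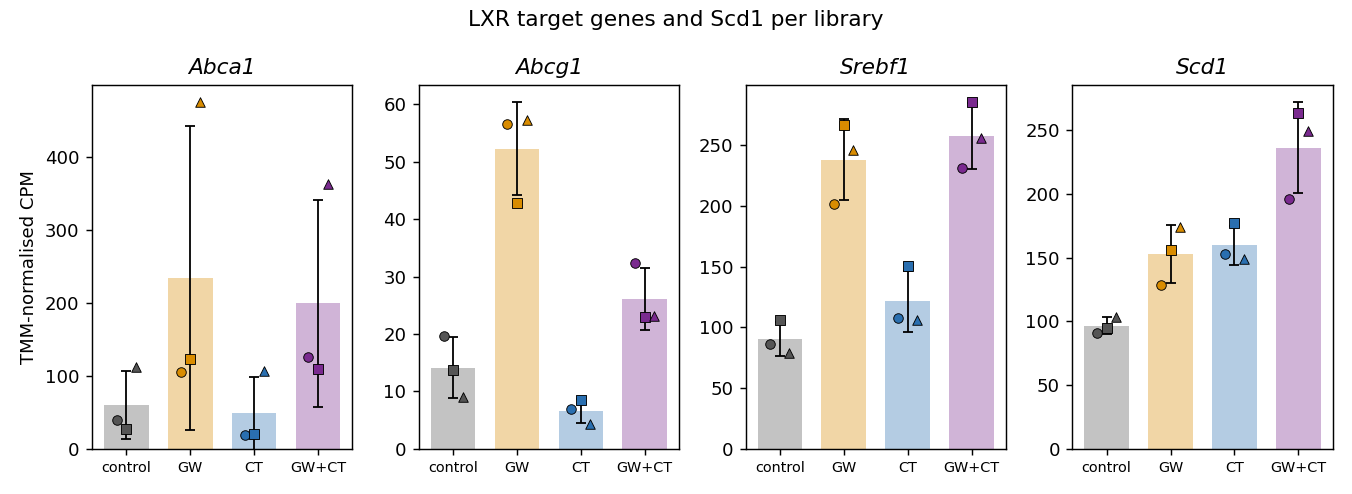
TMM-normalised CPM of Abca1, Abcg1, Srebf1 and Scd1 in the 4 groups. Bars are means, error bars SD (n = 3) and points the libraries by replicate number, and Srebf1 lies at 90.4 CPM in controls and 238 with GW3965.

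GW3965+CT99021 against CT99021 asks what GW3965 does where GSK3 beta is inhibited. The same 3 genes rose as with GW3965 alone: Abca1 by 2.26 ± 0.18, Abcg1 by 1.98 ± 0.25 and Srebf1 by 1.10 ± 0.09 (edgeR adjusted p = 0.0013, 0.0496 and 0.0013 with the block), each higher in 3 of 3 replicate pairs. Under 20 alternatives Abca1 and Srebf1 always passed and Abcg1 passed in 9, with a highest adjusted p of 0.428. Among single libraries left out it passed without control replicate 3, CT99021 replicate 2 or GW3965 replicate 3, and it did not pass without any 1 of the other 9. Without the block 0 genes passed in edgeR (165 at an unadjusted p under 0.05, 1017 with the block), DESeq2 called 2 without and 13 with the block, and limma-voom without the block 0. The count of 165, but not that of 1017, lies under the share of 0.05 of genes expected with no change. Of 16 LXR targets these 3 rose, and the median of the list was 0.00 although camera called it higher (adjusted p = 0.00812, and adjusted p = 0.391 with an estimated correlation). Cholesterol genes were lower (0 of 24 past the test, median -0.20, camera adjusted p = 2.3e-06, and adjusted p = 0.391 with an estimated correlation), and the stress list had a ratio of 1.73 in replicate 3, -0.10 in replicate 1 and -0.05 in replicate 2. The count with the block was 10 without GW3965+CT99021 replicate 3, 9 without the libraries numbered 3 and 90 in the 7 libraries outside the set of 5.

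Across all 15608 genes, the effects of GW3965 without and with CT99021 correlated weakly (Pearson r = 0.220, Spearman rho = 0.211, and r = 0.167 with the block), and genes are not independent replicates. In the fit without the block r was -0.103 without CT99021 replicate 3 and 0.00500 without GW3965 replicate 3. Such a refit leaves a group short of a replicate number, and replicate number set the largest differences between libraries. These values therefore cannot tell an unstable effect from lost balance, and r was not refitted this way with the block.

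GW3965+CT99021 against GW3965 asks the converse, what CT99021 does where LXR is activated. Axin2 rose by 1.73 ± 0.14, Notum by 2.84 ± 0.17, Lef1 by 1.88 ± 0.19 and Scd1 by 0.63 ± 0.10, and Olig2, Wnt1 and Nipal3 fell by 2.12, 1.83 and 2.55. Of 16 Wnt targets 12 rose and 1 fell. Abcg1 was lower with CT99021 here too, at 26.2 ± 5.4 CPM against 52.3 ± 8.12 (log2 fold change -1.02 ± 0.22, edgeR adjusted p = 0.0106). With the block edgeR called 3218 genes, 1843 higher and 1375 lower, and without it 12, of which 11 were lower (3 and 4 without GW3965+CT99021 replicates 1 and 2, and 4, 7 and 6 without GW3965 replicates 1, 2 and 3). DESeq2 called 464 and 3416. The count with the block was 1396, 1484, 1625 and 2078 without GW3965 replicate 1, GW3965 replicate 2, GW3965+CT99021 replicate 2 and GW3965+CT99021 replicate 1, 1648 with a batch term, and 3642 in the 7 libraries.

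The effects of CT99021 without and with GW3965 were close. Across genes r was 0.668 (Spearman rho = 0.689), and 0.667 with the block. Of the genes that rose with CT99021 in each background (1285 and 1843), 1032 were shared, against 152 for independent lists, and of those that fell (1185 and 1375), 861 were shared, against 104, while 0 went opposite ways. Among the genes called with CT99021 alone 99.3% had the same sign with GW3965 present, and the median ratio of the log2 fold changes was 0.97. In the fit without the block r was 0.268 without CT99021 replicate 3. That refit leaves the CT99021 group short of a replicate number, so it cannot tell an unstable effect from lost balance. No such refit of r was made with the block.

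**Figure D5:**
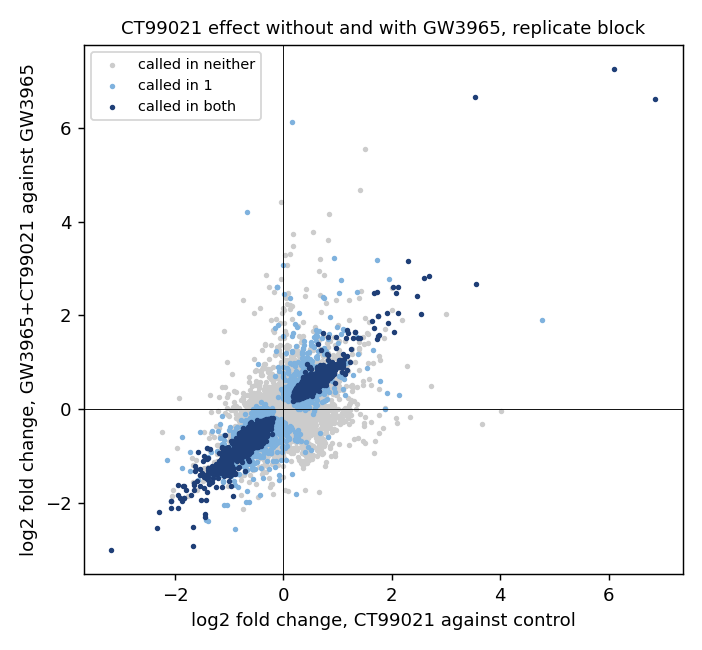
Log2 fold change of each of 15608 genes for CT99021 against control (x axis) and for GW3965+CT99021 against GW3965 (y axis), replicate block. Dark points are genes past the test in both, of which 1032 were higher in both and 861 lower in both.

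The interaction asks whether one compound changes the effect of the other. In edgeR 0 genes passed, without the block (74 at an unadjusted p under 0.05) and with it (523). Both counts lie under the share of 0.05 of genes expected with no change. DESeq2 called 0 in both forms, and limma-voom without the block 0. For Abca1, Srebf1 and Axin2, which answered to a compound alone, a difference was therefore not detectable here. In data simulated without replicate effects the interaction test recovered 0%, 4% and 42% of genes changed by 0.5, 1 and 2 log2 units without the block. With the block, in data simulated with such effects, it recovered 8%, 52% and 70%, so 0 calls do not show that interactions are absent. Among the alternatives of the fit with the block, the fit to the 7 libraries outside the set of 5 called 60 genes, 55 of them with a negative interaction, and it rests on 1 library with both compounds that is assumed to vary like the other groups. The effects of GW3965 and CT99021 against the shared control correlated at r = 0.0523, and at 0.0847 with the block, where unchanged groups simulated against the same controls gave 0.408 to 0.521. The covariance with the block was 0.00919 against a simulated mean of 0.0339, a difference of -0.0247. With the block and all libraries the observed values lie below the simulated ones. The r of the fit without the block depended on single libraries, and unchanged groups were not simulated for these refits: it was 0.326, 0.241 and 0.588 without control replicates 1, 2 and 3, -0.0256, -0.00459 and 0.254 without CT99021 replicates 1, 2 and 3, and 0.00890 and -0.0252 without GW3965 replicates 2 and 3. The 3 control libraries cannot be halved into 2 each. Of the 3 genes that rose with GW3965, 1 (Srebf1) also rose with CT99021, against 0.247 for independent lists, a difference to which the shared controls may add, and 1 (Abcg1) fell.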

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

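Of the tests in this part, those of the noncoding RNAs Rmrp, Rpph1 and Terc, of Lars2 in the other libraries with CT99021, of the stress list in replicates 1 and 2, of a mixture of RNAs, and the number of receptor genes with a count were chosen after the result was seen.

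Repeat families, which no comparison of genes used, were high in CT99021 replicate 1. The 7SL RNA row held 1047 CPM there against at most 6.60 in a control, the 7SK row 120.4 against 5.30, and the gamma satellite row GSAT_MM 1904 against 22.99. Tested row by row, 301 repeat rows gave 0 calls in edgeR in every contrast, without and with the block. At an unadjusted p under 0.05 were 2 and 5 rows for GW3965 against control and 15 and 18 for CT99021 against control. For GW3965+CT99021 they numbered 13 and 27 against control, 40 and 50 against CT99021 and 22 and 42 against GW3965. For the interaction they numbered 26 and 46. Several of these counts exceed the share of 0.05 of rows expected with no change.

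In the same library Lars2 took 7.95% of gene counts, and a candidate explanation is more RNA without poly(A) tails: Rmrp, Rpph1 and Terc summed to 148 times the highest other library. Small nucleolar RNA genes (40.1 CPM) lay within the range of the others (16.8 to 107.7). They were above the other libraries numbered 1 (16.8 to 28.6) and under CT99021 replicate 2 (48.7). Hist1 genes held 881 CPM there and 245 to 380 elsewhere. The mitochondrial ribosomal RNA genes mt-Rnr1 and mt-Rnr2 held 2519 and 6349 CPM, against at most 1163 and 1969 (1968.5) elsewhere. A response to CT99021 is argued against, since the other 5 libraries with the compound reached 1.49 times the highest control share of Lars2, though that lies just under the bound of 1.5, which was set afterwards. Genomic DNA stays open: receptor genes silent in brain summed to 1.11 times the highest other library, under the bound of 1.5 set beforehand, but 3 of their rows hold 55.5% to 76.9% of that sum in every library, so the sum says little about the others. Of 1517 receptor genes 367 had a count there against at most 117 elsewhere, and a further set of silent families, fixed beforehand, gave 1.67, between its bounds of 1.3 and 2. Ribosomal RNA repeat rows were near empty everywhere (a ratio of 0), which decides nothing, so more ribosomal RNA in CT99021 replicate 1 stays open. The gene row Mir5109 was high in that library as well, at 671 CPM against at most 10.7 elsewhere.

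Stress genes were high in the replicate 3 libraries with GW3965, with a median log2 ratio of 1.78 without and 1.73 with CT99021. Target genes of the transcription factor ATF4 outside the list were higher too in both pairs of that replicate, with a smaller median of 1.38, so an ATF4 response in those libraries is a candidate explanation. Cells of another type are argued against, because over the lists of other cell types the highest of the smaller medians of the 2 pairs was -0.109. A response to GW3965 in every replicate is argued against by replicates 1 and 2, whose medians reached 0.0146 at most. Whether the cells of replicate 3 answered to GW3965 in this way, or these libraries were handled apart, was not tested and rests on 1 library per group.

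The 4 libraries numbered 3 and GW3965+CT99021 replicate 2 stood apart from the other 7 in 215 gene rows, a set found by looking through receptor genes, with a ratio of 1.5 chosen afterwards. Olfr1123, for example, had 0 counts in the 7 libraries and 7.39 to 10.2 CPM in the 5. A shared batch of preparation or sequencing is a candidate explanation, because 14 repeat families separated the 5 libraries and at most 1 did so when another library took the place of GW3965+CT99021 replicate 2. Each of 3 index labels used by 2 libraries had 1 in the 5 and 1 in the 7. But 0 index labels were repeated within a replicate number either, so they do not tell this set from batches by number. A mixture of number 3 RNA into GW3965+CT99021 replicate 2 would put its genes at a common fraction of the way to number 3, but the interquartile range over 28 genes was 72.2%. No biological explanation was tested, and as the 5 hold 2 of 3 libraries with both compounds, part of the difference of that group from the others stays open.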

How the results depend on the processing

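The fits with the replicate block under other settings, those without locus rows and Lars2, and all refits of the correlation against the shared control were chosen after the data were seen, and the others were planned. What caused a change was not tested.

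Without the block edgeR called 0 genes for GW3965 against control, 9 for CT99021 against control, 18 for GW3965+CT99021 against control, 0 against CT99021 and 12 against GW3965. The block took these to 3, 2470, 3163, 3 and 3218, with the 9, 18 and 12 genes among them, and rests on numbers that pair the libraries (18 pairs with r of 0.496 to 0.828). DESeq2 without the block called 2, 321, 573, 2 and 464. With 2 groups only there were 0 for CT99021 against control and 2 each for both compounds against control and against GW3965. A stricter low-count filter gave 16, 28 and 20 for these 3. For CT99021 against control there were 16 without factors and 5 with a fold threshold of 1.2, and 21 for both compounds against GW3965 without locus rows and Lars2. GW3965 against control and both compounds against CT99021 had 0 in all other alternatives without the block, and the interaction 0 in all of them (edgeR, 23, 165 and 74 at an unadjusted p under 0.05). Each of these counts lies under the share of 0.05 of genes expected with no change.

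Leaving out 1 library gave 3 to 7 for CT99021 against control (3 without control replicate 1, control replicate 3 or CT99021 replicate 1, and 4 without control replicate 2 or CT99021 replicates 2 or 3). It gave 4 to 21 for both compounds against control (9, 8 and 9 without controls 1, 2 and 3, and 9, 4 and 11 without GW3965+CT99021 replicates 1, 2 and 3) and 3 to 14 against GW3965 (3 and 4 without GW3965+CT99021 replicates 1 and 2, and 4, 7 and 6 without GW3965 replicates 1, 2 and 3).

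With the block, GW3965 against control had 5 without a filter, 7 in DESeq2, 5 in the 7 libraries outside the set of 5, 1 without control replicate 2 or 3 and 5 without CT99021 replicate 3. CT99021 against control had 475 with a fold threshold of 1.2, 3869 without the libraries numbered 3, 5398 in the 7 libraries, and 652 to 3003 leaving out 1 library (747 and 652 without controls 1 and 2, 1075 and 1114 without CT99021 replicates 1 and 2). Both compounds against control had 748 with the threshold, 1539 with a batch term and 1175 to 3760 leaving out 1 (1326, 1175 and 2054 without controls 1, 2 and 3, and 1526 without GW3965+CT99021 replicate 2). Against GW3965 there were 778, 1648 and 1396 to 3683 (1396 and 1484 without GW3965 replicates 1 and 2, 2078 and 1625 without GW3965+CT99021 replicates 1 and 2). Against CT99021 there were 13 in DESeq2, 9 without the libraries numbered 3, 90 in the 7 libraries and 2 to 10 leaving out 1 (10 without GW3965+CT99021 replicate 3). The interaction had 60 in the 7 libraries and 0 in the other 19 fits with the block.

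Lists called by camera without the block numbered 7 for GW3965 against control: 1 with an estimated correlation, 1 with fry, 4 to 10 leaving out 1 library (4 without GW3965 replicate 3). For CT99021 against control there were 3: 0, 0, 5 with the block, and 3 to 6 (5 without control replicate 3, 6 without CT99021 replicate 1 or 2). For both compounds against control there were 8: 0, 1, 14 with the block, and 3 to 9 (3 without GW3965+CT99021 replicate 3). Against CT99021 there were 7: 0, 0, 13 with the block, and 4 to 9 (4 without CT99021 replicate 3 or GW3965+CT99021 replicate 3). Against GW3965 there were 5: 0, 0, 3 with RLE factors, and 3 to 8 (3 without GW3965+CT99021 replicate 3 or GW3965 replicate 1, 8 without GW3965 replicate 2). The interaction had 0 lists, and 0 to 5 leaving out 1: 2, 1 and 1 without controls 1, 2 and 3, 3 without CT99021 replicate 2, 4, 1 and 1 without GW3965+CT99021 replicates 1, 2 and 3, and 4 and 5 without GW3965 replicates 2 and 3.

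With the block an estimated correlation left 0 lists in every contrast, so a call lost with it does not tell lists apart. Fry, which tests a list against no change and not against other genes, called 1 where camera called 9 for GW3965 against control, 2 and 5 for CT99021 against control, 11 and 14 for both compounds against control, 0 and 13 against CT99021, and 10 and 7 against GW3965. Without the libraries numbered 3 there were 3 in place of 9 for GW3965 against control, 6 in place of 14 for both compounds against control, 6 in place of 13 against CT99021 and 3 in place of 0 for the interaction. Without GW3965+CT99021 replicate 2 there were 8 in place of 13 (15 without CT99021 replicate 1) and 2 in place of 0.

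Correlations with a library left out are from the fit without the block, where a group then lacks a replicate number. Across genes the GW3965 effects without and with CT99021 (r = 0.220) gave -0.103 without CT99021 replicate 3, 0.00500 without GW3965 replicate 3 and at most 0.298. The CT99021 effects (r = 0.668) gave 0.268 without CT99021 replicate 3 and at most 0.639 leaving out 1. Effects against the shared control (r = 0.0523) gave -0.0256, -0.00459 and -0.0252 without CT99021 replicate 1, CT99021 replicate 2 and GW3965 replicate 3, 0.00890 without GW3965 replicate 2, 0.326, 0.241 and 0.588 without controls 1, 2 and 3, and 0.254 without CT99021 replicate 3. Of 570 named results without the block 290 stayed on their side of the threshold under each alternative, and of 284 with the block 121, with 0 reversed in either.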

Other observations

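The lists of ribosome biogenesis, FoxO target and lysosome genes were made after the top genes with CT99021 were seen, and the check of transcript length was also chosen after the result was seen. Members such as Nolc1 and Irs2 are among the genes with the smallest p with CT99021, so the p of these lists, adjusted over these 3 and the ATF4 list alone, are weak support.

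Ribosome biogenesis genes, which make and modify ribosomal RNA, rose with CT99021: 20 of 20 passed with the block, with a median log2 fold change of 0.59. Rrp9 rose by 1.05 ± 0.13, Gnl3 by 0.96 ± 0.16, Nop2 by 0.90 ± 0.12 and Nolc1 by 0.68 ± 0.06 (89.6 ± 26.5 to 144.1 ± 45.2 CPM, SD, n = 3). With an estimated correlation the limma camera adjusted p was 0.0376, 0.0373 for both compounds against control, 0.067 in GW3965+CT99021 against GW3965 (20 of 20 rose) and 0.244 without the block (0 of 20 passed).

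Target genes of FoxO transcription factors were lower with CT99021: 10 of 22 fell and 0 rose, with a median of -0.22. Irs2, which relays insulin signals, fell by 0.91 (109.2 ± 23.8 to 58.2 ± 13.3 CPM, SD, n = 3), the ubiquitin ligase gene Fbxo32 by 1.09, Gabarapl1 by 0.69 and the autophagy kinase gene Ulk1 by 0.54. The limma camera adjusted p with an estimated correlation was 0.0376 in CT99021 against control, 0.0373 in GW3965+CT99021 against control (9 fell and 1, Gadd45a, rose), 0.067 in GW3965+CT99021 against GW3965 (8 fell, 0 rose) and 0.244 without the block. Lower lysosome genes are argued against, since 6 of 23 rose, 0 fell and the median was 0.15 (adjusted p = 0.425 with an estimated correlation).

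Removing the trend with transcript length left the genes lower with CT99021 in both backgrounds nearly unchanged. Over 861 genes the median log2 fold change was -0.58 before and -0.57 after. These genes were longer (median 3829 bases, against 2963 for tested genes and 2756 for those higher in both). The trend over all tested genes was weak (Spearman rho = -0.111), so its removal could shift genes picked as lower only little and does not exclude a part for length. Krt1, a keratin, had 75.7 CPM in CT99021 replicate 3 and at most 6.52 in any other library.

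Camera with the block did not call the following lists, fixed beforehand, in CT99021 against control. Here edgeR with the block called 2470 of all 15608 genes, so a few called members of a list can match the share over all genes. Among 10 p53 targets Pmaip1, Phlda3 and Cdkn1a rose (Cdkn1a by 0.93 ± 0.22) and Bbc3 fell, and among 12 glycolysis and hypoxia genes Pfkfb3, Aldoa and Hk2 rose and Egln3 fell. In the Shh pathway 1 of 11 rose and 2 fell, with a median of 0.00, and in the Notch pathway Hey1 and Lfng fell. Of 14 pan-neuronal genes Elavl4, Mtap2, Dcx and Snap25 fell and Nefm and Tubb3 rose. Ret and Th fell among dopaminergic neuron genes, and Nkx2-2, Slc17a6 and Tal1 among those of other midbrain neurons. Nkx2-2, Olig1 and Olig2 fell in the oligodendrocyte lineage. Gja1 rose and Slc1a2 and Aldoc fell among astrocyte genes, Cx3cr1 fell in the list of microglia and Kdr in that of endothelium. Twist1 rose in the mesenchyme list, Hsph1 rose among heat shock genes and Dusp1 fell among immediate early genes. DNA replication, erythroid, neural crest and stress lists had 0 members past the test in edgeR with the block.

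In GW3965+CT99021 against CT99021 camera with the block called 13 lists, each lost with an estimated correlation. Besides the LXR, cholesterol and stress lists, fatty acid synthesis, endothelium and mesenchyme were higher, and other midbrain neurons, proneural factors, DNA replication, oligodendrocyte lineage, microglia, erythroid cells and neural crest lower, with 0 members past the test. The lowest adjusted p with an estimated correlation was 0.391.

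Splits of the 6 libraries of a comparison into 3 and 3 number 10, too few for a share under 0.05. Without the block the real and highest other counts were 0 and 0 for GW3965 against control (10 of 10 splits as large), 9 and 0 for CT99021 against control, 18 and 0 for both compounds against control, 0 and 0 against CT99021 (10 of 10 as large) and 12 and 0 against GW3965, where for those with calls 1 split, the real one, was as large. With the block they were 3 and 0 for GW3965 against control, 2470 and 0 for CT99021 against control, 3163 and 7 for both compounds against control and 3218 and 9 against GW3965, again with 1 split as large. For both compounds against CT99021 they were 3 and 14, with 2 of 10 splits as large. The real split and 3 others part all 3 replicate pairs, and those 3 gave 0, whereas the 7, 9 and 14 came from splits that part 1 pair. For the interaction, 40 of 40 regroupings called as many genes as the real count of 0, and 1 of them called 1160 while the other 39 called 0 (edgeR, 74 at an unadjusted p under 0.05 in the real grouping). With a real count of 0 every regrouping is as large, so this comparison decides nothing about the interaction. These regroupings were run without the block only, and they mix replicate numbers and treatments. A regrouping with so many calls points to a structure of the samples, and which structure set it apart was not identified. Libraries did not overlap between groups in 2.77% of genes for GW3965 against control, 14.8% for CT99021 against control, 17.3% for both compounds against control, 2.84% against CT99021 and 15.4% against GW3965, where chance gives 10% for exchangeable libraries, which libraries paired by number are not.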
